A study of Mus musculus with 38 samples.

How the data were processed

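The series holds 38 mouse samples. RNA sequencing libraries with processed files made up 14 of them, in 7 groups of 2, and these were analysed. The other 24 samples, of chromatin immunoprecipitation and of open chromatin, are not analysed here. Per the labels' protocols, polyadenylated RNA was purified, a strand-specific library was made by digesting the uridine-containing cDNA strand, and 50-nucleotide reads were taken on an Illumina HiSeq instrument. Per the submitters' processing notes, TopHat 1.4.1, HTSeq 0.5.3, DESeq 1.8.3, SICER and the mouse genome build mm9 were used, with no role or order stated. The gene annotation, and whether gene counting used strand, are not given in the sources used here, so values of genes that overlap another gene, and of close paralogs, are less certain.

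The authors deposited RPKM values (reads per kilobase of transcript, scaled to library size) for every RNA library. For the 8 libraries of activated B cells, pre-plasmablasts, plasmablasts and Blimp1-deficient pre-plasmablasts, the deposited RPKM values were GC-normalized, per the file names, and each file lists the same 11567 entries. The 4 libraries of the inhibitor experiment hold RPKM values of 21025 entries deposited without that normalization, and so do the 2 plasma cell libraries. The GC-normalized files list fewer genes: 9240 genes of the inhibitor files are absent from them, of which 158 reached 1 RPKM in at least 1 library. Levels are therefore compared by test only among libraries of the same file type. RPKM values are not counts, so no count test was run. Entries whose name occurs more than once were left out (126 entries with 61 names in the GC-normalized files, 375 with 166 names in the inhibitor files, 420 with 188 names in the plasma cell files). Gene symbols are in capitals in the files and are printed in mouse style. Of these symbols, 11082 of 11441 in the GC-normalized files and 19204 of 20650 in the inhibitor files matched a reference table of mouse genes on assembly GRCm38. Coordinates are not printed because that assembly differs from the build of the files.

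Each plasma cell file has 5 entries without a value among the gene names, named like the summary lines of a read counter. After each of them the names stand lower than their values by the number of such entries before, so that the value of the J chain gene stood beside another gene. The names were moved back by that number. This choice was made after the values were seen, and the closing section gives the lists with the names as deposited.

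The number of reads behind the GC-normalized values is unknown, since low values fell on no common step (at most 5.6% of the genes compared shared the commonest ratio between libraries). In the inhibitor files low values lay on steps of whole reads, which gave a depth relative to the first DMSO library of 0.848 for the second DMSO library, 1.008 for the first GSK343 library and 0.832 for the second. The second plasma cell library had 0.961 of the depth of the first. In the 8 GC-normalized libraries, 9744 to 10077 genes reached 1 RPKM, and in the 4 inhibitor libraries 9188 to 9519.

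Values were analysed as log2(RPKM + 1) without further scaling, and fold changes are on that scale, which understates changes of low genes. Genes at 1 RPKM or more in at least 2 libraries were tested, 10473 in the GC-normalized files and 9479 in the inhibitor files. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided). The 8 GC-normalized libraries shared 1 fit over 4 groups, since each group had 2 libraries, and the inhibitor experiment had its own fit. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, and every adjusted p for a gene comes from limma. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Nothing in the labels says that the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

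Gene lists (24, from textbook knowledge) covered B cell transcription factors, B cell receptor signalling, major histocompatibility complex (MHC) class II and costimulation, plasma cell regulators and surface molecules, immunoglobulin genes, the unfolded protein response, translocation and vesicle transport, N-glycosylation, controllers of mTORC1, ATF4 targets, cell cycle, inhibitors of cyclin-dependent kinases, class switch recombination, migration and adhesion, Polycomb complexes, textbook Polycomb targets, the interferon response, NF-kB and activation, sterol and lipid synthesis, immediate early and heat shock genes, and markers of T, myeloid, natural killer or dendritic, and erythroid cells or megakaryocytes. Lists with at least 5 tested members (21 in each comparison) were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, with adjustment over the lists of a comparison. The estimated setting also uses the few residual degrees of freedom of the fit. A list can therefore lose its call there without correlation between its members. Members were also counted with the gene p-values adjusted over the list alone. The lists, the comparisons, the tests, most alternatives and the rule for named genes were fixed before the data were examined. That rule took, in each comparison, the 8 called genes of largest fold in each direction with no overlap between groups and a mean of at least 5 RPKM, up to 3 leading members of each list past the threshold, and Prdm1, Irf4, Xbp1, Pax5, Bcl6, Bach2, Ciita, Myc, Cd22, Sdc1, Ell2, Igj and Ezh2. Some genes that the rule names are not reported here. Other members of the lists are named as examples, chosen after their values were seen.

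The libraries of the first experiment carry numbers in 2 consecutive series, each with 1 library of every group. The differences between the series were shared by the groups (Pearson's r across genes of 0.666 to 0.781 in the 6 pairs of groups), so the series pair the libraries. Between the series limma called 4364 genes, and a term for the series lowered the median residual SD from 0.142 to 0.0801 on the log2 scale. With the series as a block, values are printed beside a gene or list where they change its call, and beside a count of called genes, in all or in a list, that they move by over 1.5 times in either direction. A series holds 1 library of each group, so no test within a series could be run.

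Further alternatives were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, quantile normalization, a fit of only the 2 groups compared, and the omission of each library in turn. Names as deposited in the plasma cell files and the series block in list tests were added after seeing the data. In simulated data with 200 changed genes, the test recovered 0% of 1.5-fold, 63.5% of 2-fold and 95% of 4-fold changes for the knockout comparison (10473 genes), and 0%, 75.5% and 96.5% for the inhibitor comparison (9479 genes). With many more genes changed the adjusted threshold is less strict, so these shares are not those of the data. In the knockout comparison 4234 genes were called, 1326 of them by 2-fold or more, with Galnt7 called at a log2 fold change of 0.39. Plasma cells and plasmablasts were compared as levels, with no test of single genes, because file type and cell origin differ together. Each list median was ranked among 10000 random lists of the same size matched on expression.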

Results

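Blimp1, encoded by Prdm1, is a transcriptional repressor that drives activated B cells to become antibody-secreting plasma cells. Gene expression was measured in mouse B cells stimulated for 4 days with lipopolysaccharide (LPS), a bacterial cell wall component that activates B cells. The cells carried a GFP reporter in the Blimp1 gene and were sorted by GFP and CD138 (syndecan-1, encoded by Sdc1). Activated B cells were CD138– GFP–, pre-plasmablasts CD138– GFP+ and plasmablasts CD138+ GFP+. Pre-plasmablasts with a GFP allele and a floxed Blimp1 allele deleted by Cd23-Cre were sorted as CD138– GFP+ with the added requirement of high CD22, so genotype and gate differ together in the knockout comparison. A separate experiment treated control cells with GSK343, an inhibitor of the histone methyltransferase EZH2, or with its solvent DMSO, and sorted pre-plasmablasts. Plasma cells (CD28+ CD138+ GFP+) were sorted directly from mice. Each group had 2 libraries, and every mean ± SD is over these 2.

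Prdm1 was at 9.09 ± 2.33 RPKM in activated B cells, 377.7 ± 72.2 in control pre-plasmablasts, 325.9 ± 52.2 in plasmablasts and 184.8 ± 19.4 in Blimp1-deficient pre-plasmablasts. Its level in the deficient cells was lower than in control pre-plasmablasts by 1.02 ± 0.21 on the log2 scale (SE, adjusted p = 0.0102). The gene-level value includes transcripts of the GFP allele and of the undeleted parts of the floxed allele, so it does not measure functional Prdm1 and checks the genotype only in part.

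**Figure D1:**
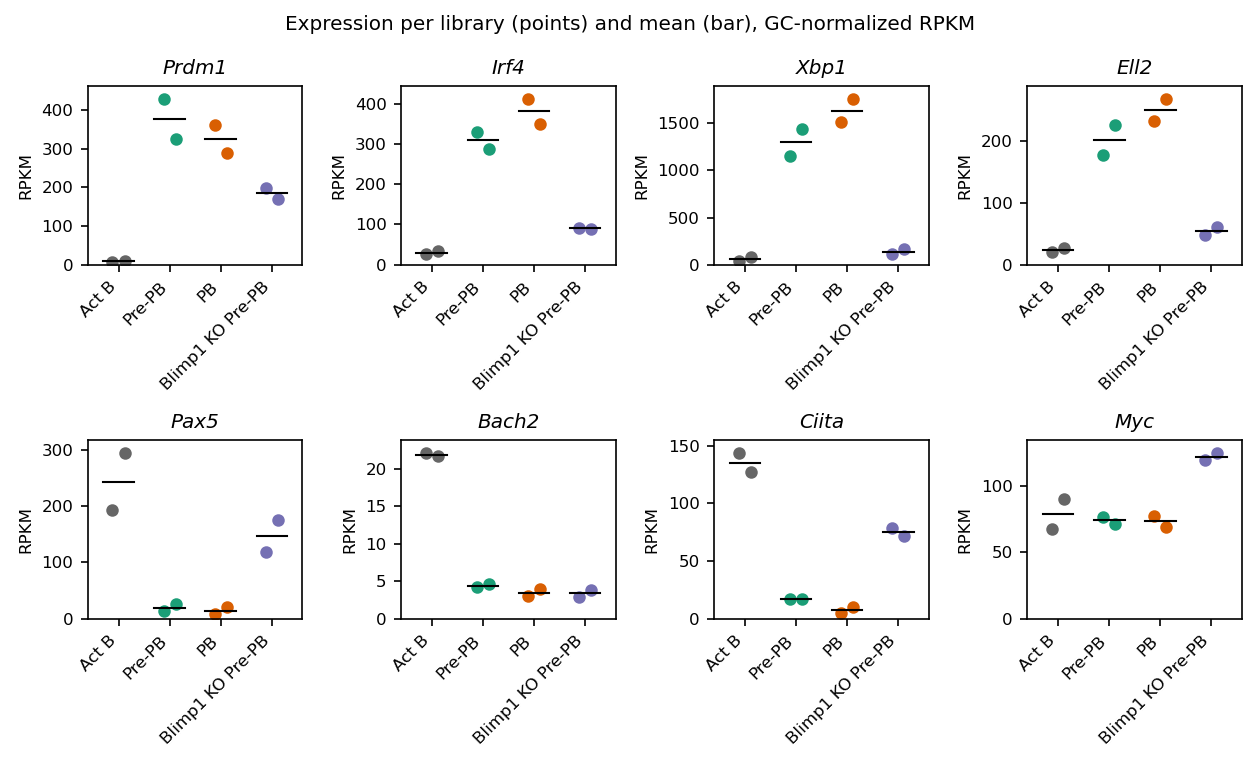
GC-normalized RPKM (vertical axes, linear from 0) of 8 regulators in activated B cells (Act B), pre-plasmablasts (Pre-PB), plasmablasts (PB) and Blimp1-deficient pre-plasmablasts (Blimp1 KO Pre-PB), with a point for each of 2 libraries and a bar for the mean. Xbp1 stands at 63.3 in activated B cells, 1300 in control pre-plasmablasts and 137.1 in deficient ones, while Bach2 is at 4.38 and 3.41 in control and deficient pre-plasmablasts.

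The comparison of pre-plasmablasts with activated B cells asks which genes change as GFP first appears. Most listed genes of the secretory apparatus and of the plasma cell programme were higher in pre-plasmablasts. Most listed B cell transcription factors, B cell receptor components, MHC class II genes and interferon response genes were lower. None of the 21 lists tested passed with an estimated correlation, the smallest being adjusted p = 0.0508, against 13 with the preset one. B cell receptor components had an estimated correlation of -0.015, under the preset one, yet their limma camera p went from 0.00016 to 0.014. The loss of that list therefore does not come from correlation between its members. J chain (Igj), which links antibody multimers, rose from 62.6 ± 78.2 to 2512 ± 1260 RPKM (log2 fold change 6.22 ± 1.34, adjusted p = 0.00881), and in activated B cells its libraries stood at 7.33 and 118 RPKM. Bhlha15, a transcription factor of secretory cells, rose from 1.47 ± 1.09 to 105.1 ± 7.68 RPKM, and the secreted protease inhibitor Slpi from 14.7 ± 13.9 to 800.1 ± 23.3 RPKM. Spib, an ETS factor of B cells, fell from 557.4 ± 15.7 to 22.6 ± 10.8 RPKM and the DNA sensor Tlr9 from 108.2 ± 1.88 to 3.90 ± 1.78 RPKM.

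Among plasma cell regulators and surface molecules, 20 of 21 tested members rose and none fell (20 adjusted over the list alone; limma camera adjusted p = 1.2e-12, adjusted p = 0.096 with an estimated correlation). That list holds Prdm1, whose GFP reporter set the gates, and Sdc1, which encodes the sort marker CD138. Irf4, a factor required for plasma cells, rose by 3.34 ± 0.14 on the log2 scale. Xbp1, the transcription factor of the unfolded protein response, rose by 4.398 ± 0.31. Ell2, an elongation factor for immunoglobulin transcripts, rose by 3.03 ± 0.19. In the unfolded protein response list 34 of 35 members rose (35 adjusted over the list alone), with a median of 2.46 and an adjusted p = 1.23e-21, adjusted p = 0.0508 with an estimated correlation. The chaperone Hyou1 rose from 47.7 ± 0.943 to 318.9 ± 7.90 RPKM and Edem2, which acts in disposal of misfolded proteins, from 27.2 ± 1.09 to 265.6 ± 21.8 RPKM. In the translocation and vesicle transport list 42 of 45 members rose (42 adjusted over the list alone; adjusted p = 5.1e-21, adjusted p = 0.0508 with an estimated correlation). The coat protein gene Sec24d rose from 3.84 ± 0.762 to 79.6 ± 3.60 RPKM. N-glycosylation genes rose in 24 of 31 cases, and with the library series as a block 25 rose and 2 fell (24 adjusted over the list alone; adjusted p = 4.81e-10, adjusted p = 0.0508 with an estimated correlation). The oligosaccharyltransferase subunit Ddost rose from 81.2 ± 2.01 to 562.2 ± 24.3 RPKM.

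ATF4 targets of amino acid metabolism rose in 17 of 21 cases (19 adjusted over the list alone; adjusted p = 7.89e-09, adjusted p = 0.194 with an estimated correlation). Atf4 itself rose from 193.2 ± 0.609 to 432.8 ± 13.8 RPKM. Of the mTORC1 controllers and amino acid carriers, 12 rose and 5 fell of 26 (12 and 5 adjusted over the list alone; adjusted p = 0.0166, adjusted p = 0.194 with an estimated correlation). The paired carrier subunits Slc3a2 and Slc7a5 rose by 2.18 ± 0.08 and 1.87 ± 0.09. Inhibitors of cyclin-dependent kinases rose in 5 of 8 cases (5 adjusted over the list alone; adjusted p = 0.00166, adjusted p = 0.199 with an estimated correlation). Cdkn2a rose from 20.4 ± 2.36 to 182.6 ± 8.37 RPKM. Immediate early and heat shock genes, which respond to cell handling, rose in 7 of 16 cases, and with the block 9 rose and 2 fell (7 adjusted over the list alone; adjusted p = 0.00757, adjusted p = 0.324 with an estimated correlation). The phosphatase gene Dusp1 rose from 6.27 ± 0.991 to 43.0 ± 0.418 RPKM.

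B cell transcription factors fell in 12 of 20 cases, with only Nfatc1 called higher (12 and 2 adjusted over the list alone; adjusted p = 0.0116, adjusted p = 0.237 with an estimated correlation). Pax5, which maintains B cell identity, fell from 243.1 ± 71.4 to 19.5 ± 8.55 RPKM and its partner in restraining differentiation, Bach2, from 21.9 ± 0.277 to 4.38 ± 0.296 RPKM. Bcl6, the germinal centre repressor, was at 8.15 ± 1.18 and 6.50 ± 1.21 RPKM (adjusted p = 0.216, with the library series as a block 0.021). B cell receptor components fell in 17 of 23 cases and rose in 2 (17 and 2 adjusted over the list alone; adjusted p = 0.00048, adjusted p = 0.0737 with an estimated correlation). Cd22 fell from 481.4 ± 16.1 to 33.4 ± 6.94 RPKM. In the MHC class II and costimulation list 14 of 18 members fell and 1, the protease gene Ctss, rose (15 and 1 adjusted over the list alone; adjusted p = 0.000283, adjusted p = 0.289 with an estimated correlation). Ciita, the master activator of MHC class II, fell from 135.2 ± 11.4 to 17.0 ± 0.322 RPKM. Interferon response genes fell in 16 of 22 cases and rose in 2 (16 and 4 adjusted over the list alone; adjusted p = 0.00253, adjusted p = 0.342 with an estimated correlation). Irf7, a factor that induces interferon, rose from 30.7 ± 3.29 to 156.5 ± 9.91 RPKM. Sterol and lipid synthesis genes fell in 15 of 22 cases and rose in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.00654, adjusted p = 0.237 with an estimated correlation). With the block, B cell transcription factors had 15 down and 4 up, MHC class II genes 15 and 2, and interferon response genes 17 and 4. Scd1 fell from 484.4 ± 1.09 to 235.3 ± 15.8 RPKM.

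The class switch list had 5 members up and 5 down of 16, with the block 6 and 8 (5 and 5 adjusted over the list alone; adjusted p = 0.938). Its median of -0.24 and mean of -0.07 stood against an upward camera direction, as did the migration list's -0.12 and -0.23. Myc was at 79.0 ± 15.5 and 74.2 ± 3.55 RPKM (adjusted p = 0.692). Cell cycle genes fell in 15 of 34 cases and rose in 4 (17 and 4 adjusted over the list alone; adjusted p = 0.0665, with the series as a block 0.0467, adjusted p = 0.233 with the block and an estimated correlation). The lists of migration and adhesion (12 up and 12 down of 30, adjusted p = 0.938) and NF-kB and activation (5 up and 8 down of 19, adjusted p = 0.511) did not pass. Nor did Polycomb complexes (2 up and 6 down of 27, with the block 7 and 12, adjusted p = 0.953) and textbook Polycomb targets (5 up and 3 down of 10, adjusted p = 0.292). The Polycomb complex list too had an upward camera direction with a median of -0.02. Adjusted over the list alone, these had 13 up and 14 down, 5 and 8, 2 and 6, and 5 and 4. Ezh2, the enzyme inhibited by GSK343, was at 63.1 ± 11.1 and 98.0 ± 22.7 RPKM (adjusted p = 0.0672, with the series as a block 0.000733). Immunoglobulin constant region genes were not among the genes tested, and Igj was the 1 member of that list that was.

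Markers of other cell types went both ways. T cell markers had 2 up and 2 down of 6 (adjusted p = 0.754) and myeloid markers 2 up and 3 down of 7 (adjusted p = 0.938), with the same counts adjusted over the list alone. Their means, -0.04 and -0.37, differed in sign from their medians, 0.23 and 0.28, and from the upward camera direction. Of 4 tested natural killer or dendritic cell markers 1 rose and 1 fell. Both tested erythroid markers fell, Hbb-b1 from 9.92 to 0.494 RPKM and Car2 from 5.74 to 2.39 RPKM.

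In all, limma called 5048 of 10473 genes, 2117 higher and 2931 lower in pre-plasmablasts, and 896 and 864 of these by 2-fold or more. With median-of-ratios scaling the split was 2461 higher and 2259 lower (52.1% higher against 41.9%), and the median log2 fold change of all genes moved from -0.12 to -0.01.

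**Figure D2:**
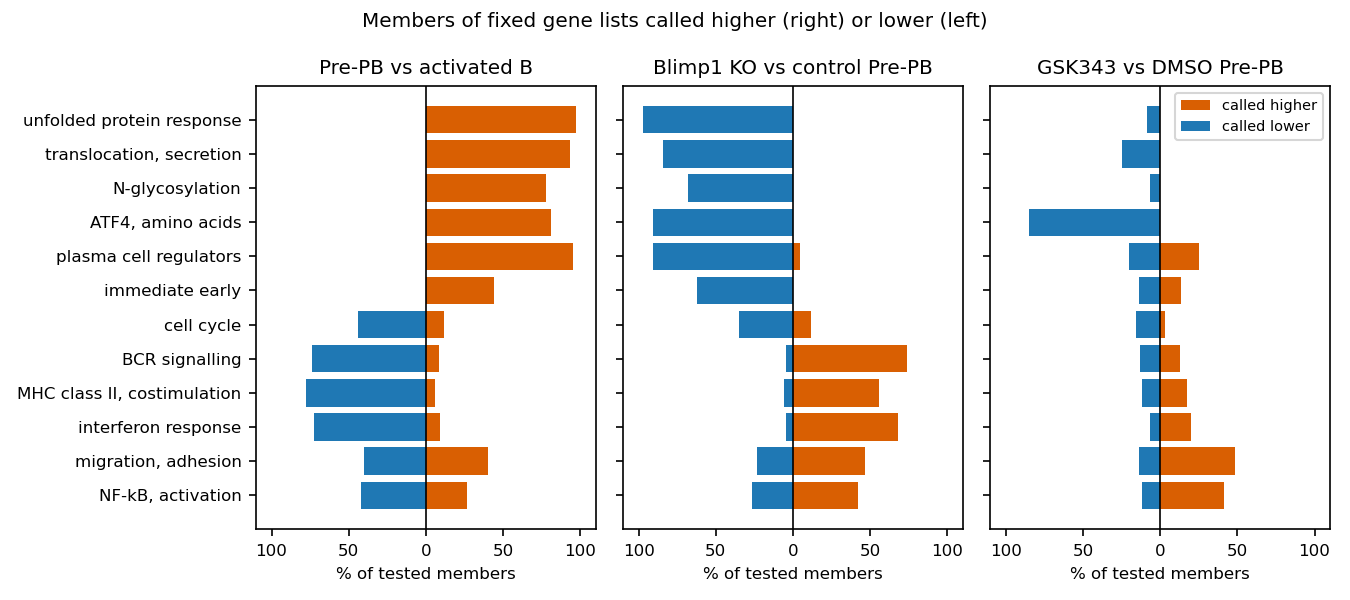
Share of the tested members of 12 gene lists called higher (orange, to the right) or lower (blue, to the left), in percent, for pre-plasmablasts against activated B cells, Blimp1-deficient against control pre-plasmablasts, and GSK343 against DMSO. In the unfolded protein response list 34 of 35 members were higher in the first comparison and 34 were lower in the second, and among ATF4 targets 17 of 20 were lower in the third.

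The step from pre-plasmablasts to plasmablasts, which were separated by CD138, involved fewer genes. Sdc1 and Tnfrsf17, which encode surface molecules of plasma cells, were among the genes that rose, and 5 of 18 MHC class II and costimulation genes fell. Sdc1, which encodes the sort marker CD138, rose from 2.16 ± 0.048 to 31.6 ± 1.57 RPKM (log2 fold change 3.37 ± 0.15, adjusted p = 7e-04). Tnfrsf17, the survival receptor BCMA, rose from 1.12 ± 0.352 to 10.5 ± 0.104 RPKM (adjusted p = 0.00278) and Ly6c1 from 5.70 ± 1.18 to 22.3 ± 4.24 RPKM (adjusted p = 0.0114). The lipid carrier gene Apoe fell from 386.1 ± 68.5 to 42.9 ± 11.6 RPKM, Ltb, a cytokine of lymphoid tissue, from 109.7 ± 26.3 to 13.0 ± 4.99 RPKM, and the phosphodiesterase Pde2a from 8.45 ± 0.108 to 0.786 ± 0.042 RPKM.

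Of the plasma cell regulators and surface molecules 5 of 21 rose (8 adjusted over the list alone; adjusted p = 1.09e-08, adjusted p = 0.123 with an estimated correlation). With the series as a block 10 rose and 1 fell. Prdm1, Irf4, Xbp1 and Ell2 did not pass, with adjusted p of 0.757, 0.374, 0.721 and 0.517, and with the series as a block Ell2 had 0.00885. In the MHC class II list 5 of 18 members fell (11 down and 1 up adjusted over the list alone; adjusted p = 6.02e-07, adjusted p = 0.199 with an estimated correlation). With the block 14 fell and 1 rose. H2-Aa fell from 1714 ± 143 to 687.2 ± 104.9 RPKM. Ciita was at 17.0 ± 0.322 and 7.81 ± 3.59 RPKM (adjusted p = 0.0966, with the block 0.013). Migration and adhesion genes fell in 7 of 30 cases and rose in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.00102, adjusted p = 0.106 with an estimated correlation). With the block 13 fell and 3 rose. Cxcr5, a follicle homing receptor, fell from 40.3 ± 3.08 to 12.6 ± 1.98 RPKM. NF-kB and activation genes fell in 4 of 19 cases (5 adjusted over the list alone; adjusted p = 0.000361, adjusted p = 0.106 with an estimated correlation). With the block 9 fell. Nfkbie fell from 73.4 ± 6.97 to 29.7 ± 0.472 RPKM. Of 10 textbook Polycomb targets 3 fell, Sox4, Wnt10b and Cdkn2a (3 adjusted over the list alone; adjusted p = 0.00842, adjusted p = 0.362 with an estimated correlation).

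Among markers of other cell types, Flt3, a receptor of dendritic cell and lymphoid precursors, fell from 16.7 ± 1.23 to 7.30 ± 0.362 RPKM (adjusted p = 0.00669), the 1 called of 4 natural killer or dendritic cell markers. Adjusted over the list alone 3 of these fell and 1 rose, as with the block, with Batf3 at 6.20 and 1.79 RPKM. Of 7 myeloid markers none was called (3 down and 1 up adjusted over the list alone and with the block; adjusted p = 0.234), with Tyrobp at 3.49 and 0.907 RPKM. T cell markers had no call of 6 (1 down adjusted over the list alone and with the block; adjusted p = 0.842).

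The secretory lists moved up as lists with few single calls. In the unfolded protein response list the median was 0.27 and 1 of 35 members, Edem2, was called (6 adjusted over the list alone; adjusted p = 2.86e-10, adjusted p = 0.106 with an estimated correlation), and 19 were called with the block. The translocation list had a median of 0.22 with no call (0 adjusted over the list alone; adjusted p = 2.75e-08, adjusted p = 0.106 with an estimated correlation), and 20 calls with the block. N-glycosylation genes had a median of 0.20 with no call (0 adjusted over the list alone; adjusted p = 9.19e-06, adjusted p = 0.106 with an estimated correlation), and 14 with the block. Among 21 ATF4 targets Pycr1 alone was called (1 adjusted over the list alone; adjusted p = 0.00133, adjusted p = 0.362 with an estimated correlation), and 7 with the block. B cell receptor genes, with 1 of 23 called lower, had an adjusted p = 0.00171, adjusted p = 0.106 with an estimated correlation (5 adjusted over the list alone), and 11 were called lower with the block. Interferon response genes, with Ifih1 and Ifit1 called lower of 22, had an adjusted p = 0.00348, adjusted p = 0.362 with an estimated correlation (4 adjusted over the list alone), and 7 were called lower with the block. With the block, Cd79a (8.73e-05), Vav2 (0.00409), Dhx58 (0.00355) and Pax5 (0.049) also passed as lower, and Bcl6 (0.00737) as higher.

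Ezh2 was at 98.0 ± 22.7 RPKM in pre-plasmablasts and 58.6 ± 15.4 in plasmablasts (adjusted p = 0.186, with the block 0.0028), and Igj at 2512 ± 1260 and 7071 ± 3530 RPKM (adjusted p = 0.70). Limma called 245 genes, 75 higher and 170 lower, and with median-of-ratios scaling 103 and 139 (42.6% higher against 30.6%). The count depended on the spread and on single libraries: with the series as a block it was 2128, with only these 2 groups in the fit it was 1. Without a pre-plasmablast library it was 26 in both cases, and without the first or second plasmablast library 23 or 68. It was 128 or 129 without an activated B cell library, and 154 or 152 without a knockout library.

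Activated B cells and plasmablasts are the ends of the path in culture. Between them Igj rose to 7071 ± 3530 RPKM (log2 fold change 7.72 ± 1.34, adjusted p = 0.00287) and Slpi to 1882 ± 35.3 RPKM. Pik3cg, the catalytic subunit of phosphoinositide 3-kinase gamma, rose from 1.68 ± 1.48 to 175.0 ± 4.86 RPKM, and the inhibitory receptor gene Tigit from 1.95 ± 1.33 to 138.6 ± 1.197 RPKM. Cd22 fell to 23.0 ± 11.97 RPKM and Ciita to 7.81 ± 3.59 RPKM. Limma called 5775 genes, 2228 higher and 3547 lower, and 1083 and 1245 of these by 2-fold or more. With median-of-ratios scaling the split was 2782 and 2617 (51.5% higher against 38.6%), with the median of all genes moving from -0.18 to -0.01. Of the 21 lists 13 passed, the same number as in the first step, with a smallest adjusted p = 0.0515 with an estimated correlation. Bcl6 was at 8.15 ± 1.18 and 9.75 ± 0.540 RPKM (adjusted p = 0.286, with the block 0.0429).

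Blimp1-deficient pre-plasmablasts had lower levels of most listed secretory and plasma cell genes than control pre-plasmablasts, and higher levels of most B cell receptor components. Of 20 B cell transcription factors 12 were higher, and that list did not pass. Igj was at 62.8 ± 63.1 RPKM in the deficient cells and 2512 ± 1260 in control cells (log2 fold change -5.69 ± 1.34, adjusted p = 0.0155), and Slpi at 19.2 ± 11.8 and 800.1 ± 23.3 RPKM. The chemokine Ccl22 rose from 12.6 ± 2.94 to 556.9 ± 96.6 RPKM (log2 fold change 5.36 ± 0.40, adjusted p = 0.000158). The transcription factor Mafa rose from 0.870 ± 0.503 to 56.6 ± 5.59 RPKM, Tlr9 from 3.90 ± 1.78 to 132.7 ± 0.568 RPKM and Spib from 22.6 ± 10.8 to 512.0 ± 17.2 RPKM. Vegfa, a vascular growth factor, fell from 60.1 ± 14.3 to 3.15 ± 0.536 RPKM.

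In the unfolded protein response list 34 of 35 members fell (34 adjusted over the list alone; adjusted p = 5.7e-22). Members fell in the translocation list in 38 of 45 cases (40 adjusted over the list alone; adjusted p = 3.19e-21) and in the N-glycosylation list in 21 of 31 (22 down and 1 up adjusted over the list alone; adjusted p = 5.68e-11). With the series as a block 26 N-glycosylation genes fell and 2 rose. B cell receptor components rose in 17 of 23 cases and fell in 1, Cr2 (21 and 1 adjusted over the list alone; adjusted p = 4.82e-06). These were the 4 lists that also passed with an estimated correlation, each with adjusted p = 0.0371, and with the series as a block added none did, the smallest being adjusted p = 0.22. Xbp1 fell from 1300 ± 203 to 137.1 ± 34.5 RPKM, Sec61a1, the channel of the translocon, from 486.9 ± 13.8 to 130.5 ± 4.94 RPKM and Ddost from 562.2 ± 24.3 to 115.6 ± 2.92 RPKM. Cd22, on which the deficient cells were selected, is a member of the B cell receptor list, so the gate itself favours its rise there. It was at 33.4 ± 6.94 RPKM in control cells and 327.1 ± 25.6 in deficient cells.

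Plasma cell regulators and surface molecules fell in 19 of 21 cases, and Il6ra rose (19 and 1 adjusted over the list alone; adjusted p = 6.84e-11, adjusted p = 0.127 with an estimated correlation). Irf4 fell from 309.2 ± 29.6 to 90.5 ± 1.22 RPKM and Ell2 from 201.4 ± 34.5 to 54.4 ± 9.91 RPKM. ATF4 targets fell in 19 of 21 cases (19 adjusted over the list alone; adjusted p = 2.26e-11, adjusted p = 0.15 with an estimated correlation). Atf4 fell from 432.8 ± 13.8 to 160.9 ± 2.02 RPKM. Immediate early and heat shock genes fell in 10 of 16 cases (10 adjusted over the list alone; adjusted p = 9.03e-06, adjusted p = 0.203 with an estimated correlation). Zfp36, a factor of mRNA decay, fell from 442.6 ± 77.1 to 67.5 ± 10.4 RPKM. Cell cycle genes fell in 12 of 34 cases and rose in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.00583, adjusted p = 0.203 with an estimated correlation). With the block 19 fell and 6 rose in that list, and among ATF4 targets 20 fell and 1 rose. Myc, repressed by Blimp1 in textbook accounts, rose from 74.2 ± 3.55 to 122.3 ± 3.69 RPKM (adjusted p = 0.00819), as did the D-type cyclin Ccnd3 from 17.3 ± 1.78 to 38.7 ± 0.062 RPKM.

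MHC class II and costimulation genes rose in 10 of 18 cases and Ctss fell (11 and 1 adjusted over the list alone; adjusted p = 0.00583, adjusted p = 0.374 with an estimated correlation). Ciita rose from 17.0 ± 0.322 to 75.1 ± 5.32 RPKM. Interferon response genes rose in 15 of 22 cases and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.000284, adjusted p = 0.32 with an estimated correlation). The member that fell was Irf7, from 156.5 ± 9.91 to 32.4 ± 3.00 RPKM. B cell transcription factors rose in 12 of 20 cases and fell in 2, Bcl6 and Ets1 (12 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.0938). With the block 13 of these rose and 5 fell, and 19 interferon response genes rose and 2 fell. Pax5 rose from 19.5 ± 8.55 to 146.5 ± 40.4 RPKM. Bach2 was at 4.38 ± 0.296 RPKM in control and 3.41 ± 0.644 in deficient cells (adjusted p = 0.182, with the block 0.0412). Ezh2 was at 98.0 ± 22.7 and 121.6 ± 4.86 RPKM (adjusted p = 0.311, with the block 0.0204). Migration and adhesion genes had 14 up and 7 down of 30 (15 and 7 adjusted over the list alone; adjusted p = 0.281).

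Myeloid markers rose in 4 of 7 cases (4 adjusted over the list alone; adjusted p = 0.0737, with median-of-ratios scaling 0.0462, adjusted p = 0.224 with an estimated correlation). Among them were Itgam at 0.591 RPKM in control and 11.9 in deficient cells, 10.6 in activated B cells, and Emr1 at 0.0606, 4.11 and 1.57 RPKM. T cell markers had 3 up and 2 down of 6 (3 and 2 adjusted over the list alone; adjusted p = 0.646), and Hbb-b1 was at 0.494 and 10.4 RPKM. Limma called 4234 genes, 2553 higher and 1681 lower, and 6829 with the series as a block. With median-of-ratios scaling the split was 1877 and 2036 (48.0% higher against 60.3%), and with quantile normalization 2016 and 2041 (49.7%), with the median of all genes moving from 0.12 to 0.01 under the first.

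The genes that changed between activated B cells and plasmablasts were then followed in the knockout comparison, which shares no library with the former. The deficient cells were also selected for high CD22, and Cd22 itself fell along this path. Genotype and gate therefore cannot be told apart in what follows. Of 1083 genes higher in plasmablasts by 2-fold or more, 864 were called lower in the deficient pre-plasmablasts, against 173.8 if the lists were independent, and 20 were called higher, against 264. Their median log2 fold change was -0.98 (limma camera p = 1.47e-78, p = 0.000902 with an estimated correlation). Of 1245 genes lower in plasmablasts, 1017 were called higher in the deficient cells, against 303.5, and 9 lower, against 199.8, with a median of 0.90 (p = 1.06e-45, p = 0.00861 with an estimated correlation). Across 10473 genes, which are not independent replicates, the 2 sets of fold changes had Pearson's r = -0.825 and Spearman's rho = -0.80. Among the 20 genes that were higher in plasmablasts and called higher in the deficient cells, named after their values were seen, was Anxa2, a membrane-binding protein, with 1.53 RPKM in control and 19.4 in deficient pre-plasmablasts. The haem oxygenase Hmox1 had 43.3 and 108.1 RPKM, and the aryl hydrocarbon receptor Ahr 3.73 and 9.27 RPKM.

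**Figure D3:**
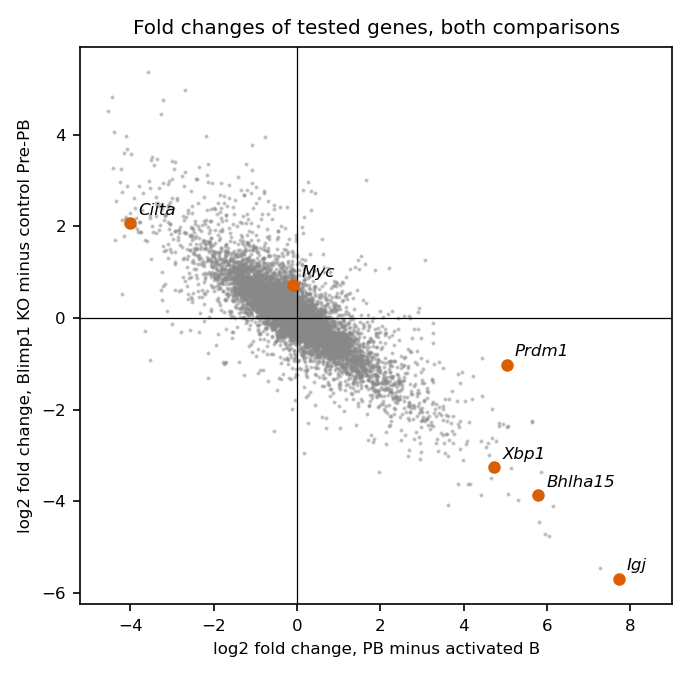
Log2 fold change of 10473 genes between plasmablasts and activated B cells (horizontal) and between Blimp1-deficient and control pre-plasmablasts (vertical), with a grey point for each gene and 6 named genes in orange. Most genes lie along a falling diagonal (Pearson's r = -0.825), with Igj at 7.72 and -5.69 and Ciita at -4.01 and 2.08.

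With GSK343, pre-plasmablasts had more of the chemokine genes Ccl3 and Ccl4 and of the homing receptor genes Ccr7, Ccr10 and Itgb7. Of 20 ATF4 targets 17 were lower. The chemokines Ccl3 and Ccl4, which attract monocytes and lymphocytes, rose from 1.93 ± 0.818 to 53.6 ± 1.01 RPKM (log2 fold change 4.25 ± 0.16, adjusted p = 1.01e-07) and from 3.30 ± 0.415 to 65.1 ± 9.35 RPKM (3.94 ± 0.12, adjusted p = 3.82e-08). Apoe rose from 4.44 ± 1.17 to 45.6 ± 6.82 RPKM and Myc from 15.7 ± 0.629 to 40.5 ± 4.51 RPKM (adjusted p = 1.39e-05). Asns, the asparagine synthetase, fell from 182.2 ± 15.5 to 66.5 ± 0.257 RPKM (adjusted p = 2.19e-06), and the lactate carrier Slc16a3 from 15.2 ± 1.69 to 2.66 ± 0.028 RPKM.

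ATF4 targets fell in 17 of 20 cases (17 adjusted over the list alone; adjusted p = 2.16e-17, adjusted p = 0.602 with an estimated correlation). Atf5 fell from 143.4 ± 18.3 to 55.5 ± 0.447 RPKM. Migration and adhesion genes rose in 14 of 29 cases and fell in 4 (14 and 4 adjusted over the list alone; adjusted p = 0.0108, adjusted p = 0.863 with an estimated correlation). The gut homing integrin Itgb7 rose from 1.56 ± 0.015 to 10.1 ± 0.527 RPKM, and the chemokine receptors Ccr7 and Ccr10 from 5.64 ± 0.447 to 16.5 ± 0.149 RPKM and from 2.50 ± 0.424 to 8.61 ± 0.687 RPKM. NF-kB and activation genes rose in 7 of 17 cases and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0361, adjusted p = 0.602 with an estimated correlation). Cd69 rose from 82.7 ± 1.92 to 136.3 ± 8.50 RPKM. Translocation genes fell in 11 of 45 cases (19 down and 1 up adjusted over the list alone; adjusted p = 7.26e-07, adjusted p = 0.602 with an estimated correlation). Unfolded protein response genes fell in 3 of 35 cases (3 adjusted over the list alone; adjusted p = 0.0155, adjusted p = 0.863 with an estimated correlation). N-glycosylation genes fell in 2 of 31 (0 adjusted over the list alone; adjusted p = 0.0361, adjusted p = 0.602 with an estimated correlation). The medians of the last 2 lists were -0.08 and -0.11, and 555 of all 9479 genes were called lower, a share near theirs. In sterol and lipid synthesis 3 genes fell and 1 rose of 23 (4 and 1 adjusted over the list alone; adjusted p = 0.0361, adjusted p = 0.863 with an estimated correlation).

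T cell markers rose in 5 of 7 cases and Cd2 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0361, adjusted p = 0.664 with an estimated correlation). Lck, the kinase of T cell receptor signalling, rose from 2.33 ± 0.187 to 8.91 ± 0.787 RPKM, while Cd3e was listed at 0 in both groups and Cd3d was at 0.0339 and 0.0856 RPKM. Myeloid markers had 2 up and 1 down of 5 (2 and 1 adjusted over the list alone; adjusted p = 0.533). Textbook Polycomb targets had 3 up, Igf2bp3, Sox4 and Wnt10a, and 1 down of 8 tested, from 38 listed (3 and 2 adjusted over the list alone; adjusted p = 0.208). Polycomb complex genes had 5 up and 2 down of 25 (7 and 2 adjusted over the list alone; adjusted p = 0.533). Ezh2 was at 28.9 ± 4.76 RPKM with DMSO and 35.8 ± 1.24 with GSK343 (adjusted p = 0.0773).

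Among regulators, Irf4 fell from 180.6 ± 10.5 to 126.8 ± 11.02 RPKM (adjusted p = 0.00226). Bach2 rose from 2.74 ± 0.178 to 5.44 ± 0.817 RPKM (adjusted p = 0.00274). Sdc1 rose from 2.79 ± 0.309 to 8.01 ± 1.05 RPKM (adjusted p = 0.000139). Prdm1 was at 107.4 ± 1.45 and 95.1 ± 16.5 RPKM (adjusted p = 0.269), Xbp1 at 2017 ± 105.2 and 1729 ± 80.4 (adjusted p = 0.13), and Pax5 at 5.53 ± 1.17 and 4.66 ± 0.462 (adjusted p = 0.402). Limma called 1763 of 9479 genes, 1208 higher and 555 lower, and 216 and 21 of these by 2-fold or more, of which 40 and 11 were at a DMSO mean of 10 RPKM or more. With quantile normalization the split was 936 and 712 (56.8% higher against 68.5%), and with no filter on low values 954 and 291 (76.6%). Without the first or second GSK343 library 914 or 876 genes were called, 659 higher and 255 lower or 682 and 194.

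**Figure D4:**
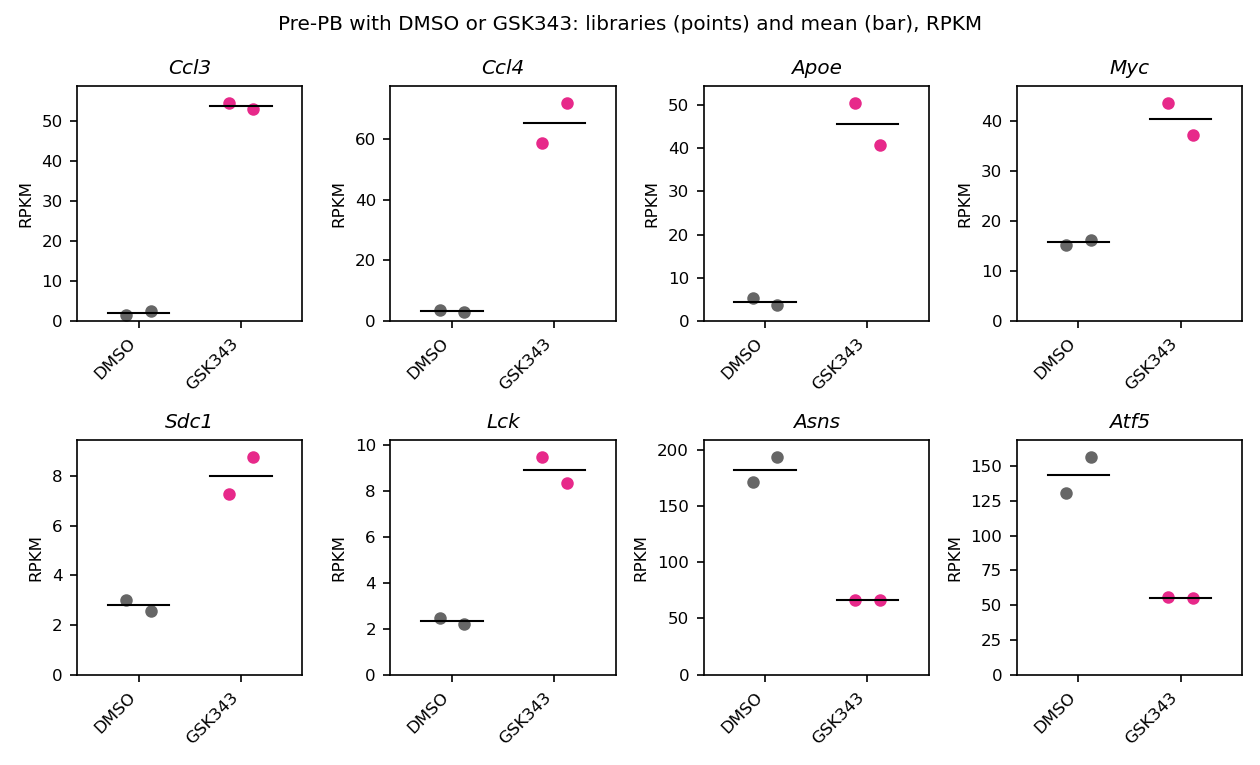
RPKM (vertical axes, linear from 0) of 8 genes in pre-plasmablasts treated with DMSO or GSK343, with a point for each of 2 libraries and a bar for the mean. Ccl3 stands at 1.93 with DMSO and 53.6 with GSK343, and Asns at 182.2 and 66.5.

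Whether the inhibitor moved the genes that differ in Blimp1-deficient pre-plasmablasts, also selected for high CD22, was tested on 9285 genes measured in both experiments. The experiments differ in file type, and some levels differed between their control groups. Ccr9 was at 0.757 RPKM in control pre-plasmablasts and 24 with DMSO, while Flt3 was at 16.7 and 18 RPKM. Of 510 genes higher by 2-fold or more in Blimp1-deficient pre-plasmablasts, 199 were called higher with GSK343, against 62.2 if the lists were independent, and 22 lower, against 29.9. Their median log2 fold change was 0.28 (limma camera p = 1.1e-12, p = 0.119 with an estimated correlation). Of 557 genes lower in the deficient cells, 125 were called lower with GSK343, against 32.7, and 103 higher, against 68.0, with a median of -0.09 (p = 0.00109, p = 0.393 with an estimated correlation). Across genes, Pearson's r was 0.212 and Spearman's rho 0.216. Spib, higher in the deficient cells by 4.52 ± 0.40, was also higher with GSK343 by 1.81, and Klf2, a factor of lymphocyte trafficking, by 4.05 ± 0.59 and 1.69.

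Plasma cells from mice were set beside plasmablasts from culture as levels. File type and origin differ together, so no gene was tested between them. List medians were placed among random lists from the same libraries, which ranks a list within this comparison and does not part cell type from file type or origin. Log2 ratios are after subtraction of the median over 9995 genes (-0.045). Sdc1 was at 766.1 ± 19.2 RPKM in plasma cells and 31.6 ± 1.57 in plasmablasts, and Tnfrsf17 at 350.1 ± 26.3 and 10.5 ± 0.104 RPKM. Igj was at 20580 ± 2960 and 7071 ± 3530 RPKM, and Xbp1 at 3283 ± 263 and 1634 ± 174 RPKM. Prdm1 was at 223.4 ± 2.12 and 325.9 ± 52.2 RPKM, and Irf4 at 319.6 ± 0.0042 and 381.5 ± 42.9 RPKM. Pax5 was at 0.191 ± 0.105 and 14.4 ± 8.67 RPKM, Myc at 15.9 ± 0.446 and 73.6 ± 5.81 RPKM, and Ezh2 at 5.63 ± 0.544 and 58.6 ± 15.4 RPKM.

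The cell cycle list had a median log2 ratio of -2.49, below all of 10000 random lists of the same size matched on expression, with Top2a at 3.91 ± 0.382 RPKM in plasma cells and 75.1 ± 6.94 in plasmablasts. Inhibitors of cyclin-dependent kinases (-1.44), sterol and lipid synthesis (-1.36), MHC class II and costimulation (-0.83), NF-kB and activation (-0.83) and ATF4 targets (-0.69) also lay at percentile 0. Natural killer or dendritic cell markers had -1.33 (percentile 0.9), from 5 genes. Of these Flt3, Eomes and Batf3 were lower in plasma cells and Prf1 and Ccr9 higher. The interferon response had -0.61 (0.8), B cell receptor components -0.43 (1.1) and B cell transcription factors -0.42 (1.8). For B cell transcription factors the spread between libraries, 0.546, exceeded that shift. Plasma cell regulators and surface molecules had 0.25 (97.5), T cell markers 0.55 (95, from 7 genes) and myeloid markers 1.92 (100, from 5 genes). Genes absent from the GC-normalized files, such as S100a8, could not enter any list. Between these lay the unfolded protein response at -0.20 (22.6), translocation at -0.15 (22.9), and N-glycosylation at -0.19 (14.6). So did mTORC1 controllers at -0.05 (38.5), class switch at -0.16 (19.1), migration and adhesion at -0.11 (27.6), Polycomb complexes at 0.04 (57.3), Polycomb targets at 0.23 (78.3) and immediate early genes at -0.31 (10.6). Among single genes, the homing receptors Ccr10 and Itgb7 were at 232.7 ± 15.1 and 212.0 ± 8.65 RPKM in plasma cells and 2.56 ± 0.220 and 3.34 ± 0.581 in plasmablasts. Other homing receptors were lower in plasma cells, with Cxcr5 at 0.232 and 12.6 RPKM and Ccr7 at 0.350 and 11.7 RPKM. Neutrophil genes in plasma cells included S100a9 at 30.5 RPKM, Ngp at 24.1 and S100a8 at 10.1, and Hbb-b1 of erythroid cells was at 38.0 ± 15.3. Fos, an immediate early gene, was at 318.1 ± 13.6 RPKM in plasma cells and 18.4 ± 8.44 in plasmablasts. It went against the median of its list, and Egr1, at 20.8 and 72.3 RPKM, and Egr2, at 1.41 and 32.5, were lower in plasma cells.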

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

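The plasma cell names as deposited and the series block in list tests were chosen only after the results were seen, and the other alternatives were planned. Of the 293 pairs of a named gene and a comparison, each under its alternatives, 3591 outcomes kept direction and side of the threshold, 178 lost the call, 33 gained it and none reversed. A fit without 1 library assumes that the lone library left in a group varies like the other groups.

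Between plasmablasts and pre-plasmablasts the count of called genes was 1 with only the 2 groups in the fit, which leaves fewer samples for the spread, 2128 with the series as a block and 23 to 154 with a library left out, against 245. In the knockout comparison the block gave 6829 against 4234, and the residual spread was lower with the block. For GSK343 a library left out gave 876 to 1951 against 1763. The counts of the other comparisons stayed within 1.5 times under the alternatives tried, with 3694 to 4844 for pre-plasmablasts and 4555 to 5646 for plasmablasts against activated B cells with a library left out. With an estimated correlation the lists past the threshold numbered 0 (pre-plasmablasts against activated B cells), 0 (plasmablasts against pre-plasmablasts), 0 (plasmablasts against activated B cells), 4 (knockout) and 0 (GSK343), against 13, 11, 13, 10 and 8. With it, the 510 genes higher and 557 genes lower in the knockout lost their calls with GSK343, at the same medians of 0.278 and -0.092. That setting also uses few residual degrees of freedom, so these losses do not measure correlation between genes alone.

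With the plasma cell names as deposited 4 list medians reversed by more than the spread between libraries: plasma cell regulators -3.04, class switch 0.34, interferon response 1.4 and natural killer or dendritic cell markers 4.04. The Polycomb complex median went from 0.04 to -0.01, within that spread, with these names and also without centring. Others moved: B cell transcription factors -2.86, B cell receptor -1.97, MHC class II -1.68, unfolded protein response -5.11, translocation -2.17, N-glycosylation -1.66, mTORC1 -0.74, ATF4 targets -3.37, cell cycle -1.34, kinase inhibitors -2.76, migration -2.07, Polycomb targets 0.71, NF-kB -1.69, sterol synthesis -2.13, immediate early -1.06, T cell markers 4.59 and myeloid markers 1.62. These values stand beside the wrong genes by the construction of that alternative. Without centring the translocation median was -0.2, by the subtracted median. For the other values that moved, the cause was not tested. The depth of the GC-normalized libraries is unknown, so what depth limits there cannot be given.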

Other observations

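Chosen only after the result was seen were the comparison of Blimp1-deficient pre-plasmablasts with activated B cells and its simulations, the tests of plasma cell names, of the second activated B cell library and of the GSK343 ratios except that at a mean of 10 RPKM, while the counts without a library were planned.

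Against activated B cells, limma called 1885 genes in the deficient cells, 1089 higher and 796 lower, and 4477 with the series as a block. Of these, 429 were higher than in both control pre-plasmablasts and activated B cells, where independent lists would share 265.5. Lower than in both were 166, where independent lists would share 127.8. By 2-fold or more against both groups, 119 were higher and 24 lower, so most of these differences were smaller. Both comparisons use the same deficient libraries, in which genotype and the gate on high CD22 differ together from the other groups. In 20 simulations that kept the levels of the other groups and held every gene of the deficient cells between them, 17.1 genes were called higher than both on average, at most 24, and 13.1 lower, at most 21. With the series as a block 975 genes were higher than both and 498 lower, where the same simulations with the block gave 32.0, at most 50, and 24.4, at most 32. Tnfsf15, a cytokine of the TNF family, was at 21.6 RPKM in deficient cells, 0.464 in control pre-plasmablasts and 1.18 in activated B cells. Cd300lf, an inhibitory receptor, was at 93.1, 5.90 and 10.8 RPKM, and Ccl22 at 556.9, 12.6 and 129.3 RPKM. Bcl6 was at 2.07, 6.50 and 8.15 RPKM, and Cox6a2, a subunit of cytochrome oxidase, at 13.2, 63.9 and 47.0 RPKM. In the cell cycle list 9 of 34 members were lower than in both groups and 1 was higher.

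In the plasma cell files many names carried implausible values. In 12 of 12 segments between the entries without a value, the best match to plasmablasts lay at the shift given by the number of such entries before the segment. After the names were moved back, the rank correlation with plasmablasts was 0.89 and 0.892 in the 2 libraries, against 0.183 and 0.182 as deposited. No other cell type was set beside plasmablasts in this way, so this correlation cannot decide whether the files hold another cell type. Names pushed down by the inserted entries are the likely cause.

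In the second activated B cell library, 19 of 19 genes picked as abundant in plasmablasts and low in activated B cells were higher than in the first. Igj was at 118 against 7.33 RPKM. These genes had at least 50 RPKM in plasmablasts and an activated B cell mean under 3% of that level. The upper cutoff leaves out genes that would imply a large share. The plasmablast RNA share implied per gene had a median of 1.2% and a middle range of 0.856% to 1.49%, in part set by that cutoff. A small share of secreting cells or their RNA may be present. Sorting, early differentiation and carry-over of RNA are not parted by these values. A difference between the series that multiplies these genes alike in every group is argued against by the same genes in plasmablasts. Their median log2 difference there was -0.08, against 0.73 in activated B cells. It was -0.1 in pre-plasmablasts and 0.09 in deficient cells. A small amount of RNA added to every library of the second series would hardly show where these genes are abundant. The plasmablast and pre-plasmablast values therefore cannot decide on such an addition. Slpi differed in deficient cells too, by 1.27, against 2.12 in activated B cells and -0.04 in plasmablasts. Igj differed in every group, by 1.06 in plasmablasts, 1.07 in pre-plasmablasts, 2.50 in deficient cells and 3.84 in activated B cells, so a series difference may be part of its rise. Without that library 4673 genes were called between plasmablasts and activated B cells and 3793 between pre-plasmablasts and activated B cells.

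With GSK343, called changes of 2-fold or more were 216 rises and 21 falls, 10.3 to 1. The second GSK343 library listed fewer genes at 0 than the others, but without it the ratio was 10.5. With quantile normalization it was 6.31, which argues against the scaling as the whole cause. Among 4993 genes at a DMSO mean of 10 RPKM or more it was 3.64, from 40 rises and 11 falls. Rises made up 78.4%, with a binomial 95% range of 64.7% to 88.7%. That range treats genes as independent, which they are not, and does not measure the spread between libraries. A floor that keeps genes low with DMSO from falling may be part of the excess. The 8.12 among genes at a mean of 10 RPKM over all libraries decides nothing, since that mean includes the GSK343 level. Relief of repression by inhibited EZH2 also stays open as untested, since no chromatin data were used here. The textbook Polycomb targets did not pass as a list, but only 8 of 38 listed were tested. Genes under the filter on low values were left out, so that result does not cover silent targets.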
